A study of Homo sapiens with 4 samples.

How the data were processed

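The data were the deposited scanner files of 4 one-colour Agilent arrays, 2 of control SH-SY5Y cells and 2 of MBD6-heterozygous SH-SY5Y cells, and a deposited table of processed values for the same arrays. Per the labels' protocols, total RNA was extracted on columns with DNase digestion and amplified into Cy3-labelled cRNA. The series design text calls the 2 samples of each group biological replicates. Samples were grouped by their titles. Per the file headers, the 4 arrays lay on 1 slide, with control samples at positions 1 and 3 and MBD6-heterozygous samples at positions 2 and 4, and were read in 1 scan, so no slide or scan differed between the groups.

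Per the file headers, the spot intensities were background-subtracted and spatially detrended by Agilent Feature Extraction, with dim spots set to a small positive value, and were not normalized between arrays. The submitters' processing notes name Agilent Feature Extraction 11.0.1.1. Spot flags and control types were also used as deposited. The deposited table holds for 24180 probes a linear ratio of each probe's signal to a constant of its array, as its values show against the scanner files. On each array 98.4% to 98.9% of those values lay within 0.1% of the median quotient, and the constants, 850 to 1048 in signal units, lay near the arrays' 75th percentiles. The column medians were 0.360, 0.368, 0.356 and 0.367 for control replicate 1, MBD6-heterozygous replicate 1, control replicate 2 and MBD6-heterozygous replicate 2. Scale and direction were thus settled and no centring was seen, while the filter behind the 24180 probes was not given in the sources used here.

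Each array held 44495 spots, 43118 of them of genes. Spots carrying an outlier flag of Feature Extraction, 343 to 469 per array, and control spots were left out. The log2 intensities of the spots of a probe were averaged, and each array's 75th percentile over gene probes was subtracted. The median coefficient of variation of repeated spots was 3.69% to 5.71%. Probes were kept if well above background on at least 2 of the 4 arrays. Gene names came from the probes' transcript accessions, matched without versions to a RefSeq table of assembly GRCh38.p14. Of 34127 probes, 25771 matched 1 symbol, 0 several and 8356 none, and the latter kept their accession or probe target name. The array design used another build, so no coordinates are given. The table also served to find which genes neighbour each other. A gene was represented by its brightest kept probe. Of 1504 called genes with several kept probes, all other probes had the same sign in 1262 and at least 1 had the opposite sign in 242.

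Groups were compared with limma (version 3.58.1, R 4.3.3) by lmFit and eBayes, without trend or robust options, and Benjamini-Hochberg adjustment over 18971 genes, calling an adjusted p under 0.05. Where a group was not well above background on either array, the change is given as a bound. It is the brighter group's mean minus the dimmer group's mean, in which each array counts at the higher of the gene's own value and the lowest value well above background on that array. Each array was counted as 1 sample, as the series design text calls them biological replicates. On probes with repeated spots, replicate arrays differed with 14.2 times the variance of spot noise in control cells and 2.42 times in MBD6-heterozygous cells, which any separate hybridisation can give. The p-values measure the spread between these samples within a group. Whether the samples of a group came from separate clones was not given, so the p-values may not cover differences between clones. All tests were two-sided.

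Lists of genes were fixed before the data were examined, as were the design and most alternatives, and 63 lists with at least 5 measured members were tested with camera at a preset correlation of 0.01, adjusted over the lists, with the estimated correlation and fry beside it. With an estimated correlation camera rests on the few degrees of freedom that 4 arrays leave. It could hardly call a list here, so its lack of calls decides nothing. Member counts are given over all genes and adjusted over the list alone. Genes named in the text followed a rule fixed before the data were examined. It took MBD6 with the called members of its family and complex, the 12 largest rises and 12 largest falls among called genes, and up to 4 called members of each called, respiratory or Polycomb list and of other lists with at least 3 called members. The largest rises and falls needed groups without overlap, the same direction in both same-numbered pairs, an official symbol and a signal well above background on both arrays of the higher group. Rises and falls were ranked by the measured change or, where it applied, by its bound. Genes of the Y chromosome and XIST were left out. Some genes that the rule takes are not reported here.

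The comparison was tested on simulated data with the means of the 18971 genes and spreads drawn from the fitted prior distribution, 20 draws with 200 changed genes each. Of genes changed by 0.5 on the log2 scale 8.8% were called, of those changed by 1 71.6%, by 2 93.0% and by 4 98.6%, and 4.46% of calls were false. A simulated fall of 0.3 in every member of the complex I list was called in 20 of 20 draws, and 3 of 1220 tests of unshifted lists were called. Genes were drawn independently of each other, so these list figures do not hold for lists whose members vary together. The draws also changed far fewer genes than were called in the data, so the figures may not carry over to them.

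Alternatives were quantile and median scaling, no filter on dim probes or a filter on all 4 arrays, every probe or the mean of probes, outlier-flagged spots kept, a trended and robust eBayes, the replicate number as a block, the deposited table, each sample left out in turn, adjusted p under 0.1, unadjusted p under 0.01 and a test against a 1.2-fold change. Chosen after seeing the data were normexp (offset 50) on the spots' median signals, cyclic loess over kept or over all probes, and scaling to the detected E1A spike-in controls. Tables and figures were made with pandas 2.3.3 and matplotlib 3.10.9.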

Results

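Gene expression was measured in SH-SY5Y cells, a human neuroblastoma line, with and without a heterozygous change of MBD6. MBD6 is a protein of the methyl-CpG-binding domain family and a partner of PR-DUB, the BAP1 complex that removes ubiquitin from histone H2A. Total RNA of 2 control and 2 MBD6-heterozygous samples, described by the submitters as biological replicates, was labelled with Cy3 and hybridised to 4 one-colour Agilent arrays on 1 slide. On the 4 arrays, 68.7% to 70.2% of the 43118 spots of genes were well above background, and 0 were saturated. The level of a gene is given as log2 of its signal relative to the 75th percentile of its array, and fold changes are MBD6-heterozygous over control, ± the standard error of the fit, with n = 2 per group throughout. The series title sets the comparison in the context of mitochondrial respiration and chromatin. The number of arrays limits the precision of each value, and whether the MBD6-heterozygous replicates came from separate clones was not given in the sources used here.

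The MBD6 transcript did not differ measurably between the groups. Its brighter probe lay at 0.84 ± 0.12 (SD, n = 2) in control cells and at 0.81 ± 0.02 in MBD6-heterozygous cells, a log2 fold change of -0.03 ± 0.08 (limma, adjusted p = 0.74). The 95% interval of this difference, -0.25 to 0.18, did not reach a 2-fold loss. The fold change turned to 0.05 without control replicate 2, and to 0.02 under both cyclic loess settings, with no call in any of them. The other probe gave -0.01 ± 0.06. The position of the edit relative to the probes was not given, so these probes could not check the labels, and every direction below is that of the arrays labelled MBD6-heterozygous.

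Among relatives and partners of MBD6, the changes were small and went both ways. Of the 10 measured members of the MBD family list, 3 rose and 1 fell. BAZ2A, a subunit of a nucleolar remodelling complex, rose by 0.47 ± 0.08. MBD5, the closest relative of MBD6, rose by 0.25 ± 0.04, and MBD4, a DNA glycosylase, fell by 0.38 ± 0.04. In the PR-DUB list 3 of 11 members rose and 0 fell, namely FOXK1 (0.47 ± 0.08), ASXL2 (0.35 ± 0.04, with another probe at 0.09) and MBD5. The catalytic subunit BAP1 gave -0.03 ± 0.09. Neither list as a whole was called by camera (adjusted p = 0.737 and 0.441), the median of the PR-DUB list turned to -0.04 under spike-in scaling, and adjusted over the list alone 3 MBD family members rose and 3 fell, and 3 PR-DUB members rose.

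A large part of the transcriptome differed between the groups. Of 18971 genes tested, 4237 were higher and 3465 lower in MBD6-heterozygous cells at an adjusted p under 0.05 (limma), and 954 were at least 2-fold higher against 233 at least 2-fold lower. These 2-fold counts were 257 and 76 under normexp, whose offset draws dim values together, and 689 and 152 among genes well above background on all 4 arrays. Of the 13923 genes matched to a protein-coding entry, 2760 rose and 2961 fell. Of the 4182 probe targets whose accession matched no gene, 1204 rose and 407 fell. These can include known genes under an unmatched accession. The deepest falls were in genes that control cells expressed at high or moderate levels. The ranking by bounds favours such genes, since a gene dim in control cells cannot show a deep fall. GAL, encoding the neuropeptide galanin, fell by 10.03 ± 0.06 on the log2 scale, from 4.13 to -5.90 (adjusted p = 0.000165). COX17, the copper chaperone of cytochrome c oxidase, was at 0.61 ± 0.20 (SD) in control cells and not well above background on either MBD6-heterozygous array, a fall of at least 160.1-fold (adjusted p = 0.00155). The unconventional myosin gene MYO16 (at least 64.0-fold), CYTL1 (at least 46.0-fold), the peroxidase GPX7 (at least 39.9-fold), CCDC152 (at least 30.9-fold) and ITM2A (at least 26.4-fold) were likewise not well above background on either MBD6-heterozygous array. FABP5, a fatty-acid-binding protein, fell by 6.17 ± 0.14, and its other probes gave -5.41 and -4.91. BASP1, a growth-cone protein, fell by 5.19 ± 0.06. SCG5, the secretory chaperone 7B2 (-4.87 ± 0.05), RNF212 (-4.63 ± 0.22, with 1 of the 2 MBD6-heterozygous arrays well above background and another probe at -2.81) and MYD88, an adaptor of Toll-like receptors (-4.47 ± 0.11), completed the 12 largest falls.

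The largest rises were smaller and began from low levels. NR0B2, a nuclear receptor without a DNA-binding domain, was at least 10.6-fold higher, the ligand gene WNT4 at least 9.44-fold, the transcription factor gene GATA5 at least 8.43-fold and SULT6B1 at least 7.68-fold, and none of these was well above background on either control array. Among genes measured in both groups, RAB37 rose by 3.25 ± 0.06 (another probe at 2.00), the GABA receptor subunit gene GABRB1 by 3.17 ± 0.04, IGSF21 by 3.15 ± 0.06, the intronic transcript ASAP1-IT1 by 3.14 ± 0.09 and the transcription factor gene PAX7 by 3.03 ± 0.09. A second PAX7 probe rose by 0.86. FGL1 (2.88 ± 0.06), the protease gene PAPPA (2.87 ± 0.11) and TENT5C (2.87 ± 0.09) completed the 12 largest rises. Altogether 81 called genes were well above background on both control arrays and on neither MBD6-heterozygous array, and 256 showed the opposite. The count of changed genes, 7702, was 2056 without MBD6-heterozygous replicate 1 and 2029 without MBD6-heterozygous replicate 2, where the lone sample was assumed to vary like the control samples. Of the called genes 55.0% were higher, and 39.2% were when the arrays were scaled to their spike-in RNAs, a setting chosen after seeing the data.

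**Figure D1:**
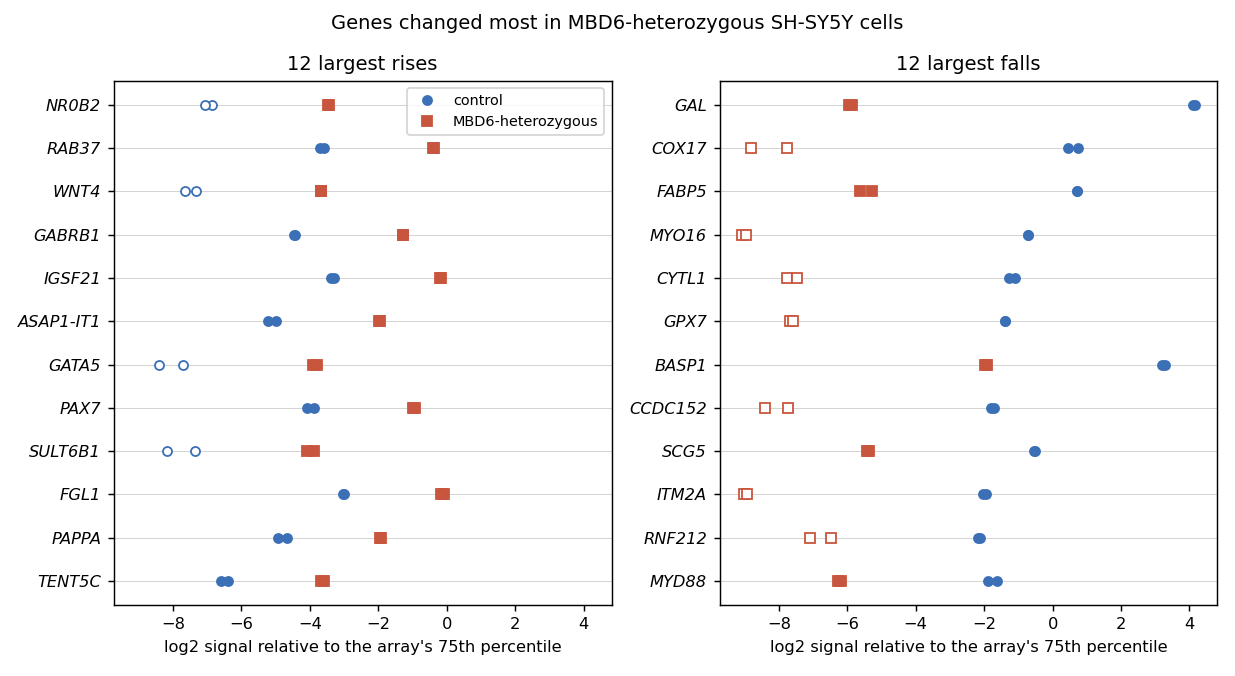
Log2 signal relative to the array's 75th percentile for the 12 genes with the largest rises and the 12 with the largest falls, 1 symbol per array (circles, control; squares, MBD6-heterozygous; open symbols, a group in which at least 1 of its 2 arrays was not well above background). GAL dropped from 4.13 to -5.90, and for COX17 the MBD6-heterozygous replicates, not well above background, lie at -7.75 and -8.82.

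The list of nuclear respiratory chain genes was called lower, with most of its members not called. Over 95 measured nuclear genes for respiratory chain subunits, with assembly factors of complexes II, III and V, the median log2 fold change was -0.09, 24 fell and 0 rose, against 17 and 0 adjusted over the list alone (camera, adjusted p = 7.32e-05; adjusted p = 0.418 with an estimated correlation). For comparison, 25.3% of all genes fell and 9.59% rose in the brightest 10%, and 27.7% fell and 11.5% rose in the 10% below it. The share of falls in the respiratory list was thus near that of other bright genes, while its share of rises, 0 of 95, lay below theirs. The list lost its call under quantile normalization, with a median of -0.05, and under cyclic loess over all probes, with a median of -0.04. Under spike-in scaling, which lowers every log2 fold change by 0.09, its median was -0.18 and it was called. In complex I, the NADH dehydrogenase, 14 of 37 nuclear subunits fell and 0 rose, with the same counts adjusted over the list alone (median -0.14, adjusted p = 0.000189; adjusted p = 0.418 with an estimated correlation). Its largest falls were those of NDUFA6 (-0.55 ± 0.09), NDUFC1 (-0.36 ± 0.05), NDUFA8 (-0.35 ± 0.04) and NDUFA5 (-0.27 ± 0.04). Of 16 complex I assembly factors 7 fell, among them NDUFAF4 (-0.54 ± 0.07) and COA1 (-0.35 ± 0.04), for a median of -0.17 (adjusted p = 0.0146; adjusted p = 0.418 with an estimated correlation). In complex V, the ATP synthase, 5 of 20 fell over all genes and 0 adjusted over the list alone, led by ATP5PF (-0.27 ± 0.05) and ATP5MF (-0.22 ± 0.04; adjusted p of the list 0.0325, and adjusted p = 0.460 with an estimated correlation). Quantile normalization and cyclic loess over all probes ended the calls of all 3 lists, cyclic loess over the kept probes those of the assembly factors and complex V, and leaving out control replicate 2 or either MBD6-heterozygous replicate that of complex V.

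Cytochrome c oxidase, complex IV, held the largest individual changes of the chain. COX4I2, an isoform of subunit 4 linked to the response to oxygen, fell by 2.42 ± 0.10 and COX6C by 0.26 ± 0.04, while 12 of the 14 measured subunits were not called and the list was not (adjusted p = 0.215, median -0.03, turning positive under both cyclic loess settings). Of 23 measured assembly factors 8 fell and 1 rose. This list lay near the threshold (adjusted p = 0.0591) and was called in 7 of 18 other settings, among them median and spike-in scaling, normexp, no filter on dim probes and leaving out either MBD6-heterozygous replicate. Besides COX17 the falls included COX20 (-0.70 ± 0.06, with another probe at -0.26), CMC2 (-0.38 ± 0.05) and COA6 (-0.29 ± 0.06). In complex II 1 of 8 genes changed, SDHAF4 (-0.36 ± 0.04; list adjusted p = 0.222). In complex III 2 of 16 did, the electron carrier CYCS (-0.33 ± 0.05, with other probes between -0.34 and 0.03) and BCS1L (-0.18 ± 0.04; list adjusted p = 0.137). The complex III list was called with no filter on dim probes and under normexp, and its median turned positive under quantile normalization and both cyclic loess settings. The respiratory subunits encoded by mitochondrial DNA were not analysed here, since no probe's accession matched them. The unmatched probes were not searched for them, so whether the array measures them was not settled.

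Of 80 mitochondrial ribosomal proteins 17 fell and 2 rose (median -0.09, adjusted p = 0.00107; adjusted p = 0.418 with an estimated correlation), and of 29 import and cristae proteins 8 fell and 0 rose, with 0 adjusted over the list alone (median -0.12, adjusted p = 0.00849; adjusted p = 0.418 with an estimated correlation). Examples were MRPS17 (-0.36 ± 0.07), MRPL10 (0.33 ± 0.06), MICOS10 (-0.37 ± 0.05, with another probe at -0.04) and TIMM21 (-0.35 ± 0.06). Both calls were lost under quantile normalization and cyclic loess. No call was made for the lists of the tricarboxylic acid cycle (adjusted p = 0.229), fatty acid oxidation (0.526), mitochondrial dynamics (0.103), chaperones and proteases (0.14), mitochondrial DNA maintenance (0.255) or SLC25 carriers (0.758). With no filter on dim probes the lists of dynamics and of chaperones were called, and under normexp that of dynamics was. Members still changed, in both directions. PDK1, a kinase that inhibits pyruvate dehydrogenase, fell by 1.26 ± 0.04, MPC1, a subunit of the pyruvate carrier, by 0.51 ± 0.05, and the mitophagy receptor BNIP3 by 0.95 ± 0.04. PPARGC1B, a coactivator of mitochondrial biogenesis, rose by 1.37 ± 0.05 and GDAP1 by 0.87 ± 0.05. ACADL, an acyl-CoA dehydrogenase, was at least 2.23-fold lower.

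Lists of mitosis, replication, cholesterol synthesis and glycolysis were called lower. Of 34 mitotic genes 29 fell and 1 rose (median -0.40, camera adjusted p = 2.35e-09), and of 36 replication genes 26 fell and 0 rose (median -0.32, adjusted p = 1.18e-08). Adjusted over the list alone, 31 fell in each. CCNA2 (-0.64 ± 0.05), CDK1 (-0.59 ± 0.05), CCNE2 (-0.63 ± 0.08) and RRM2, a subunit of ribonucleotide reductase (-0.62 ± 0.06), led these falls. In cholesterol synthesis 17 of 24 genes fell and 1 rose (20 and 1 adjusted over the list alone), for a median of -0.38 (adjusted p = 1.58e-06), with IDI1 at -0.66 ± 0.06, MSMO1 at -0.65 ± 0.04 and TM7SF2 at 0.63 ± 0.09. In glycolysis 15 of 21 genes fell and 1 rose (median -0.43, adjusted p = 5.99e-05), including PFKFB3 (-1.23 ± 0.05), LDHA (-0.68 ± 0.05) and PGK1 (-0.63 ± 0.06). For all 4 lists the adjusted p was 0.418 with an estimated correlation. Of 18 hypoxia targets 10 fell and 3 rose (median -0.53, adjusted p = 0.0257; adjusted p = 0.460 with an estimated correlation), with LOX at -1.49 ± 0.07 and ANGPTL4 at 1.04 ± 0.05, and this call was lost without control replicate 2, with every probe tested on its own and under quantile, cyclic loess and spike-in scaling.

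Lists of protein-folding genes were called lower. Of 14 cytosolic heat shock genes 9 fell and 0 rose (median -0.31, adjusted p = 0.000519), among them BAG3 (-0.87 ± 0.19) and DNAJA1 (-0.58 ± 0.05). Of 20 genes of the unfolded protein response 12 fell and 0 rose (median -0.25, adjusted p = 0.000573), among them MANF (-0.50 ± 0.05) and DNAJB11 (-0.44 ± 0.05). Adjusted over the list alone the counts were the same, and the adjusted p was 0.418 for both lists with an estimated correlation.

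Of 25 neuronal cytoskeleton and differentiation genes 13 fell and 5 rose (median -0.29, and -0.12 under normexp, where it was called, adjusted p = 0.0126; adjusted p = 0.471 with an estimated correlation). The neurofilament genes NEFM (-1.41 ± 0.06), NEFL (-1.19 ± 0.04) and NEFH (-0.92 ± 0.04) fell together with DCX (-1.38 ± 0.04), which encodes doublecortin. In the catecholamine and chromaffin granule list 10 of 21 genes fell and 4 rose (median -0.15, adjusted p = 0.0333; adjusted p = 0.418 with an estimated correlation). Its largest falls, beside GAL and SCG5, were those of the peptide gene NPY (-3.54 ± 0.05) and of SLC18A1, a vesicular monoamine transporter (-1.64 ± 0.06). This call was lost without control replicate 1, without control replicate 2 and under quantile, cyclic loess and spike-in scaling. Of 28 adrenergic identity genes 11 fell and 5 rose, with RET at -1.54 ± 0.05 and MYCN at -1.15 ± 0.04, and the list was not called (adjusted p = 0.396).

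Lists of matrix, mesenchymal, epithelial, axon guidance and protocadherin genes were called higher, with members called in both directions in all but the epithelial list. Of 34 collagen and matrix genes 19 rose and 9 fell (median 0.58, adjusted p = 0.0257; adjusted p = 0.494 with an estimated correlation), led by COL5A1 (2.86 ± 0.05), DCN, encoding decorin (2.43 ± 0.05), COL3A1 (2.22 ± 0.05) and COL1A1 (2.16 ± 0.06). Among 22 markers of the mesenchymal neuroblastoma state, a second cell state that such cultures can hold, 12 rose and 4 fell (median 0.36, adjusted p = 0.0254; adjusted p = 0.418 with an estimated correlation). YAP1 rose by 1.72 ± 0.04 and PDGFRA fell by 1.71 ± 0.05. The largest changes of this list were those of COL3A1 and COL1A1, which the matrix list also holds, so the calls of these lists are not independent. Of 10 epithelial markers 6 rose and 0 fell, among them KRT18 (0.97 ± 0.07) and EPCAM (0.93 ± 0.05; adjusted p of the list 0.0146, and adjusted p = 0.418 with an estimated correlation). Without control replicate 2 these 3 lists were no longer called, nor was the matrix list without control replicate 1 or the epithelial list with no filter on dim probes. Of 33 axon guidance genes 16 rose and 5 fell (median 0.20, adjusted p = 0.0146; adjusted p = 0.418 with an estimated correlation), with SEMA3F at 2.19 ± 0.10, SEMA5A at 1.63 ± 0.05 and the netrin receptor gene UNC5D at -2.86 ± 0.10. Of 35 clustered protocadherin genes 19 rose and 3 fell (median 0.26, adjusted p = 0.00186; adjusted p = 0.418 with an estimated correlation), for example PCDHGB4 (1.11 ± 0.07) and PCDHGB3 (at least 1.72-fold higher). Probes of such near-identical genes, and those of histones and HLA genes, can bind transcripts of their relatives.

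Lists of p53 targets, histones, MHC class I and cytosolic ribosomal proteins were called higher. Of 26 p53 targets 13 rose and 0 fell (15 and 0 adjusted over the list alone), for a median of 0.29 (adjusted p = 0.000312; adjusted p = 0.418 with an estimated correlation), with SPATA18 at 1.32 ± 0.06 and ZMAT3 at 0.68 ± 0.04. Among 62 replication-dependent histone genes 34 rose and 7 fell (median 0.40, adjusted p = 0.00343; adjusted p = 0.668 with an estimated correlation), including H2BC26 (1.96 ± 0.04) and H3C15 (1.69 ± 0.05), and the call was lost without control replicate 2. Of 10 genes of MHC class I antigen presentation 6 rose and 0 fell (median 0.29, adjusted p = 0.0146; adjusted p = 0.418 with an estimated correlation), with TAP2 at 0.86 ± 0.07 and HLA-B at 0.45 ± 0.08 (another probe at 0.17). The 57 cytosolic ribosomal protein genes had a median of 0.14, which ranged from 0.05 under spike-in scaling to 0.21 under cyclic loess over all probes with the call kept (adjusted p = 0.000311; adjusted p = 0.605 with an estimated correlation), where 9 rose over all genes and 0 adjusted over the list alone, with RPL29 at 0.25 ± 0.04 (other probes between 0.10 and 0.21).

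In PRC2, which methylates histone H3 at lysine 27, EZH2 (-0.43 ± 0.07) and PHF19 (-0.41 ± 0.05) fell and 9 of 11 members were not called (list median -0.15, adjusted p = 0.0258; adjusted p = 0.460 with an estimated correlation), and the list call was lost under quantile normalization and cyclic loess. In PRC1, which ubiquitinates histone H2A, 8 of 24 members fell and 5 rose, with CBX7 at 0.60 ± 0.09 (another probe at 0.35), CBX2 at -0.46 ± 0.04 (another at -0.77) and BMI1 at -0.45 ± 0.08 (list adjusted p = 0.322). Among 466 genes with ZNF symbols, most of which encode zinc-finger proteins, 142 fell and 42 rose (median -0.12, adjusted p = 5.99e-05; adjusted p = 0.418 with an estimated correlation), with ZNF630 at -1.41 ± 0.05 (another probe at -0.82) and ZNF521 at -1.16 ± 0.05.

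Altogether 26 of the 63 lists were called with camera's preset correlation, 9 higher and 17 lower. With an estimated correlation 0 were called by camera at an adjusted p under 0.05, and 6 had an unadjusted p under 0.05, the smallest being 0.0246. That test rests on the few degrees of freedom that 4 arrays leave, so a call over 63 lists was hardly within reach. Its lack of calls therefore decides nothing about the lists. Fry, which asks whether the genes of a list move one way on balance and does not compare them with other genes, called 44. Adjusted over the list alone, rises and falls numbered 1 and 17 for the mitochondrial ribosome, 1 and 7 for complex I assembly, 1 and 16 for glycolysis, 5 and 10 for hypoxia, 5 and 14 for the neuronal, 4 and 11 for the catecholamine, 21 and 9 for the matrix, 13 and 4 for the mesenchymal and 7 and 0 for the epithelial list. They were 18 and 5 for axon guidance, 20 and 3 for protocadherins, 34 and 7 for histones, 7 and 0 for MHC class I, 0 and 2 for PRC2 and 42 and 142 for ZNF symbols. Median, mean and test differed in sign for 8 lists, all of them uncalled, including those of the MBD family, SLC25 carriers and mitochondrial DNA maintenance. The medians of the 26 called lists kept their sign under quantile, median, cyclic loess and spike-in scaling. Their size moved by over 1.5 times for several. Over all settings the medians ran from -0.22 to -0.06 for complex I, -0.26 to -0.10 for its assembly factors, -0.20 to -0.05 for complex V, -0.18 to -0.03 for the mitochondrial ribosome, -0.21 to -0.06 for import, -0.24 to -0.09 for PRC2 and -0.21 to -0.06 for ZNF symbols. They ran from -0.29 to -0.08 for the catecholamine, -0.62 to -0.26 for the hypoxia, 0.18 to 0.65 for the matrix, 0.16 to 0.43 for the mesenchymal, 0.30 to 0.48 for the epithelial, 0.11 to 0.23 for the axon guidance and 0.18 to 0.32 for the protocadherin list.

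**Figure D2:**
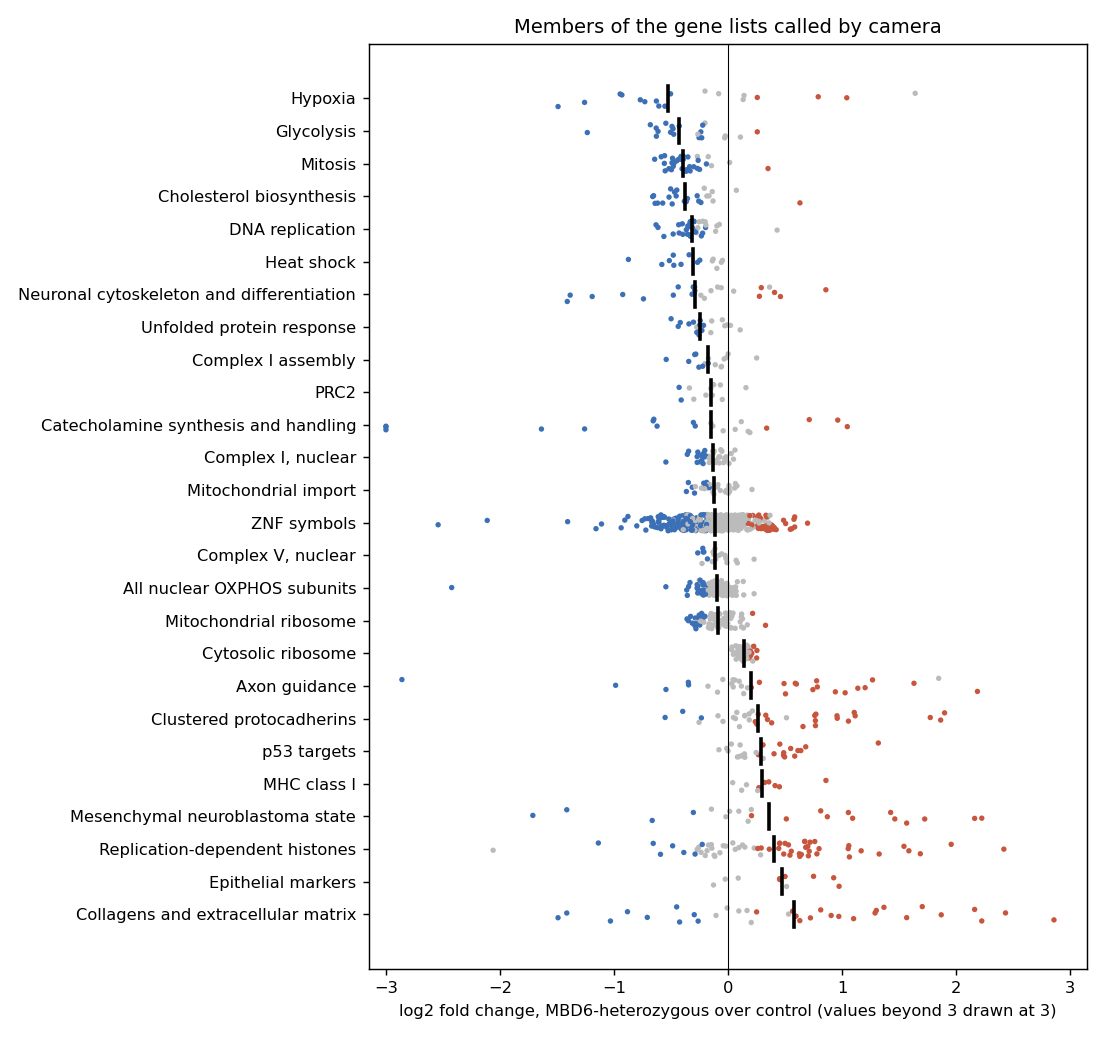
Log2 fold change (MBD6-heterozygous over control) of every measured member of the 26 lists called by camera, 1 point per gene (red, called higher; blue, called lower; grey, not called), with a black line at each list's median. Medians run from -0.53 for hypoxia targets to 0.58 for collagen and matrix genes, and 3 values below -3 are drawn at -3.

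The size and direction of change also followed signal level. In the dimmest 10% of the genes the median log2 fold change was 0.27 and 290 genes were at least 2-fold higher against 73 at least 2-fold lower. Toward bright genes it sank to -0.09 in the last group but 1, and in the brightest 10% it was -0.06, where 9.59% of genes rose and 25.3% fell. The median level of the respiratory list was 3.83, that of the glycolytic list 3.30 and that of the mitotic list 2.41, against -1.66 for the matrix list and -4.11 for the clustered protocadherins. The 8 detected E1A spike-in controls of the array differed by 0.09 on average, with differences of 0.12 at the lowest and 0.11 at the highest detected level.

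**Figure D3:**
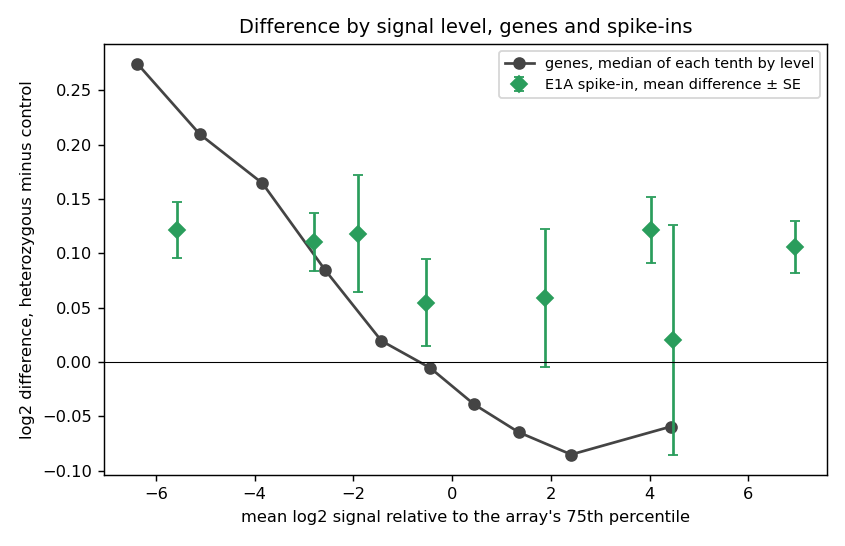
Log2 difference between MBD6-heterozygous and control arrays against mean log2 signal relative to the 75th percentile (circles, medians of groups of 10% of the genes by level; diamonds, detected E1A spike-ins, mean difference ± SE, n = 2 per group). The gene medians decline from 0.27 to -0.06 while the spike-in differences stay between 0.02 and 0.12.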

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

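The normexp, cyclic loess and spike-in settings were chosen after the data were seen, and the cause of each change below was not tested unless its construction shows it. The count of changed genes, 7702 (4237 higher, 3465 lower), ranged from 2029 to 8767 when each sample was left out in turn (1517 to 4897 higher, 512 to 3870 lower), and was lowest without either MBD6-heterozygous sample, where the spread came from the control pair. With no filter on dim probes, which adds genes to the test, 4559 were changed and 1679 lower. Against a 1.2-fold change 2710 were (1982 higher, 728 lower), and normexp gave 6885 higher. With the replicate number as a block 6610 were changed (3882 higher, 2728 lower). The deviations of same-numbered samples correlated at 0.069 across genes, so little shared deviation was seen. Whether these samples shared a culture or labelling day was not given, and so few arrays cannot exclude it. The other settings gave counts within 1.5 times, and 39.2% of calls were higher under spike-in scaling against 55.0%. MBD6 was not called in any setting and its fold change ranged from -0.12 to 0.052 without 1 sample and was 0.021 under cyclic loess over kept and 0.015 over all probes. The respiratory list lost its call under quantile normalization (-0.051), cyclic loess over all probes (-0.043) and an estimated correlation (median -0.093). Of 26 lists 17 were called under quantile normalization, 17 under cyclic loess over all probes and 0 with an estimated correlation, which has little power on 4 arrays. Fry called 44, and 63 for change in either direction. No chromosome was called in the main setting, and 10 were with no filter.

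Uncalled lists whose test turned were fatty acid oxidation under quantile normalization (median -0.035), the MBD family under quantile normalization (-0.037) and cyclic loess over kept probes (-0.012), and SLC25 carriers under quantile normalization (0.054) and cyclic loess over kept (0.055) and all probes (0.070). Uncalled genes that turned were ASXL3 (-0.013 under median scaling, -0.072 under spike-in scaling, -0.014 to 0.048 without 1 sample), BAP1 (0.00088 under quantile normalization, 0.028 and 0.019 under cyclic loess, -0.14 to 0.077 without 1 sample), FOXK2 (0.030, 0.043 and 0.029 under quantile normalization and cyclic loess over kept and all probes), HCFC1 (-0.0038) and OGT (-0.039) under spike-in scaling, and MBD1 with the mean of its probes (0.042). Under normexp, whose offset draws dim values together, KCNK10 (0.046), ZNF662 (0.0031) and ZNF883 (0.0076) turned and lost their calls. They were not well above background on either MBD6-heterozygous array, and their falls were at least 1.39-, 1.16- and 1.45-fold. Of the other values of named genes 4253 kept side and direction, 393 lost a call and 24 gained one. Most calls were lost without MBD6-heterozygous replicate 1 (113) or 2 (110). A slide or scan block was not run, as there was 1 of each, nor was normexp on mean signals, which the columns used here do not hold. On each array 68.7% to 70.2% of spots were well above background.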

Other observations

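Other gene groups changed in both directions. In the interferon list 7 of 20 measured genes rose and 5 fell, with ISG15 at 2.01 ± 0.07 and BST2 at 1.60 ± 0.09 (log2 fold change ± SE, n = 2 per group), and the list was not called by camera (adjusted p = 0.344). Of 19 Notch pathway genes 8 rose and 5 fell, with the ligand gene DLL1 at 2.75 ± 0.05 and JAG2 at 1.41 ± 0.07 (list adjusted p = 0.197). Of 28 WNT pathway genes 14 rose and 5 fell (adjusted p = 0.07, and 0.0482 under cyclic loess over kept probes). Among TGF-beta and BMP genes, INHBA fell by 3.29 ± 0.05 while TGFB1 rose by 1.84 ± 0.09 and the BMP antagonist GREM1, well above background on 1 of the 2 control arrays, by 2.63 ± 0.11 (6 of 20 rose, 3 fell, adjusted p = 0.875). Of 31 imprinted genes 10 rose and 7 fell, among them NDN, at least 5.22-fold lower, and the antisense transcript KCNQ1OT1, which rose by 2.40 ± 0.04 (adjusted p = 0.915). In the HOX clusters HOXC8 rose by 2.09 ± 0.05 and HOXD3 fell by 1.68 ± 0.05 (2 of 14 rose, 4 fell, adjusted p = 0.94).

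Genes usually silent outside pluripotent or germ cells included NANOG, at 1.87 ± 0.11, POU5F1, at 1.29 ± 0.09, and MAGEC1, at 1.45 ± 0.05 (another probe at 2.69), of 11 measured genes of which 4 rose and 3 fell (adjusted p = 0.725), and pseudogenes of the first pair have near-identical sequence. In the list of related neurodevelopmental disorders 8 of 25 genes rose and 2 fell (adjusted p = 0.551), with KMT2D at 0.92 ± 0.05, KMT2A at 0.79 ± 0.04 and KMT2C at 0.63 ± 0.09. In the DNA methylation list TET1 rose by 0.65 ± 0.05 at its brighter probe, whereas its other probe gave -0.03, and UHRF1 fell by 0.43 ± 0.04 (adjusted p = 0.615). Of 21 measured neighbours of MBD6 in the genome 6 rose and 1 fell (adjusted p = 0.72). Of 9 Schwann and glial markers 4 rose and 1 fell (adjusted p = 0.0898), and of 8 haematopoietic markers 1 rose and 2 fell (adjusted p = 0.844). Of 23 chromosomes camera called 0, also with an estimated correlation. At an unadjusted p under 0.05 there were 2 and 0, and the medians ran from -0.09 on chromosome 4 to 0.06 on chromosome 21.

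The tests at matched brightness, the cyclic loess settings and the comparison of splits were chosen after the results were seen. The first pattern was the trend with signal level, in which dim genes were higher and bright genes lower. The tables argue against a brightness-dependent response of the arrays, since a straight line fitted to the 8 detected spike-ins fell by 0.040 ± 0.044 (SE) over their range of levels, while a line fitted to the gene trend at the same levels fell by 0.28. One curve for every gene would shift all targets of a level alike, and in the brighter part they did not shift alike. There, targets not matched to a protein-coding gene lay 0.13 above protein-coding genes at matched level (bootstrap 95% interval 0.11 to 0.15). In the dimmer part they lay only 0.020 above them (-0.003 to 0.04). Of these 5048 targets over all levels 4182 matched no gene and may include coding transcripts, so coding and noncoding genes were not compared. A curve shared by all dim genes therefore stays open, as does a biological difference of the MBD6-heterozygous cells in low-level transcription, which was not tested.

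The second pattern was the set of 81 genes, COX17 among them, that were well above background on both control arrays and on neither MBD6-heterozygous array. Many of them were dim in control cells and had bounds near 1-fold, such as SEMA3G (1.04), APCDD1 (1.04) and LPL (1.07), so the set is not one of deep falls. Loss of a chromosome segment would lower the neighbours too, but the nearest measured protein-coding genes had a median of -0.030 (bootstrap 95% interval -0.11 to 0.04). These were 106 neighbours of the 53 protein-coding members, of which 5 fell and 3 rose by over 1. The median takes small and deep falls together, so it cannot exclude a loss at single genes. The neighbours of COX17, POPDC2 and CFAP91, gave 0.28 and -1.13. A sequence variant under a probe could also remove a signal. Of the 3 other detected probes of these genes 100% fell by over 1 on the log2 scale, but with an exact binomial interval of 29.2% to 100% this decides nothing, and for COX17, with 1 probe, it was not testable. Neighbours of the 256 genes with the opposite pattern had a median of 0.07 (0.02 to 0.12), against -0.01 for all protein-coding genes. This comparison was not matched on level, and the median of protein-coding genes was 0.11 in the dimmer and -0.07 in the brighter part. The trend with signal level is therefore not excluded for these neighbours. A difference between cell clones that is unrelated to MBD6 stays open, since the origin of the replicates was not given.

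The third pattern was the lower median of the nuclear respiratory list. The brightness trend of all genes may account for part of it. Among 10000 random lists matched on level the median of the respiratory list, -0.09, stood at percentile 9.24, inside the central 95%. After cyclic loess its median was -0.05 over kept probes, where it was still called, and -0.04 over all probes, where it was not, so the trend as the whole cause cannot be told apart from a shift of the list. The mitotic, replication, cholesterol and glycolytic lists stood at percentile 0 in the same comparison and were called under both cyclic loess settings. Other called lists lay inside the central 95%, namely the mitochondrial ribosome (31.1), PRC2 (14.9), complex V (14.0), mitochondrial import (10.7), complex I (5.89), complex I assembly (4.63), catecholamine (2.81) and protocadherin lists (95.6), so the trend is not excluded for them either. The median of the protocadherin list was 0.26 and after cyclic loess over kept probes 0.27, and the list stayed called under both cyclic loess settings, which speaks against the trend as its cause, but its percentile leaves this open.

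The count of changed genes, 7702, was the highest of the 3 splits of the 4 arrays into pairs, and 1 of the 3 reached it. The other splits called 0 genes with limma, with 120 and 86 at an unadjusted p under 0.05, fewer than the 949 expected without any difference. Each group of those splits held 1 control and 1 MBD6-heterozygous array. The difference between the real groups therefore widened their spread, which made calls unlikely, and they give no baseline for the count. So few splits cannot give a share under 0.05. A difference between cell clones that is unrelated to MBD6 stays open for this count and for the list calls too.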
